A study of Drosophila melanogaster with 8 samples.

How the data were processed

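RNA from whole pupae was measured by sequencing in 8 libraries, 4 of pupae that developed at 3 g and 4 of 1 g controls. Per the labels, each library was made from polyadenylated RNA of a pool of 4 pupae of the Canton-S strain, kept at 25 °C, with a TruSeq mRNA kit, and all 8 were read as paired ends of 100 bp in 1 lane of a HiSeq-2000. The labels gave the group and the replicate number of every library. Beyond the pools, nothing says that replicates came from separate cultures, so p-values measure the spread between these pools.

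Per the submitters' processing notes, the tools CASAVA, Trimmomatic 0.30, Bowtie2 2.1.0, eXpress 1.5.1 and DESeq were used, with no role or order given. The genome build and the annotation of the deposited values are not given in the sources used here, nor is whether reads were counted by strand, so a gene and one that overlaps it on the other strand cannot be told apart. The deposited table holds 1 value per gene and library as a whole number, treated here as a score and read as TPM (transcripts per 1000000) multiplied by 100 and rounded. How the authors made the table is not stated. That reading rests on the table's own name, which says normalized TPM, and on each library summing to 1000000 after division by 100, within rounding, as raw counts of 8 libraries would not. Whether the word normalized means a further scaling, for example with DESeq, is not given in the sources used here. Values were divided by 100 to give TPM. TPM keeps no record of how many reads a library held, so depth is unknown and no counting interval or floor is given. A gene listed at 0 is described as such. Because TPM is a share of each library, a group of genes that takes a larger share lowers the values of the rest.

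The table lists 13918 genes by name, of which 135 were at 0 in every library. Names were compared with the gene table of RefSeq for the assembly Release 6 plus ISO1 MT, used only for names and for which genes lie beside each other. Of the names, 11959 equalled a current symbol, 1843 matched through a synonym and 116 did not match, and genes are named as in the deposited table. No positions are given, since the build of the values is not given in the sources used here. Among tested genes, 154 fell into 61 sets that hold identical values in all 8 libraries. A gene in such a set is not measured apart from the others.

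Genes with a mean of at least 1 TPM over the 8 libraries were tested, 12044 in all. A linear model of log2(TPM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and no covariate, and p-values were adjusted by the method of Benjamini and Hochberg, with 0.05 as the threshold. The prior had 2.00 degrees of freedom. The model and the list test were first tested on simulated data with the means and spreads of the genes in these libraries. Of 50 genes changed by each size, 28 (2-fold), 43 (4-fold), 46 (8-fold) and 49 (16-fold) were called, and 8 of all 174 calls (4.60%) were of unchanged genes. The simulated noise was independent between genes and equally wide in every library, and the simulated lists held genes drawn at random. In these data members of a list can vary together and libraries were unequal, so the rate of false calls may differ here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

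A total of 36 gene lists were fixed, covering pathways, timing of development and markers of cell types that whole pupae hold. Members were taken by gene symbol. Some patterns took genes outside the sense of the list: that for cytochrome P450s took the cyclophilin gene Cyp1, and that for male germline genes took the Toll-related gene MstProx and accessory gland genes. The fat body list shares its larval serum protein genes with the list of salivary glue and early prepupal genes. For each list, members past the threshold were counted over all genes tested and again adjusted over the list alone. Lists of at least 3 members were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 36 lists. A list score is the mean over members of the log2 deviation from each gene's average over the libraries. The genes roX1 and roX2 were not analysed here.

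Genes are named by a rule. It took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 TPM whose 4 values at 3 g all lay above or all below those of the controls. It also took up to 4 members of each list with the smallest adjusted p past the threshold, or up to 2 where none passed, and the reference genes RpL32, Act5C, alphaTub84B and Gapdh2. The lists, this rule, the model and the alternatives that follow were chosen before the data were examined. The alternatives were a pseudocount of 0.1 or 1, no filter, a minimum of 5 TPM, median-of-ratios rescaling, quantile normalization, no trend, a robust fit, sample weights, the replicate number as a block, each library left out in turn, a minimum change of 2-fold, and the estimated correlation. Chosen after seeing the data were the fit without 3 g replicate 2 and control replicate 4, the library of each group with the lowest mean correlation with the others of its group, a fit with the male germline score of each library as a covariate, and a fit with genes of identical values counted once.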

Results

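Whole pupae of the wild-type Canton-S strain of the fruit fly Drosophila melanogaster were compared between 2 groups. In one group development took place at 3 g, that is, in hypergravity, and in the other, the control, at the normal 1 g. The question named by the series is how the transcriptome of pupae responds to development in hypergravity. All pupae were collected at stage P6, an early stage of pupal life. Each group had 4 libraries of polyadenylated RNA, and each library came from a pool of 4 whole pupae, so that a value sums over all tissues. The labels used here do not give the sex of the pupae. Levels are given in transcripts per 1000000 (TPM), as mean ± SD over the 4 pools of a group (n = 4 each). Fold changes are given as log2 of TPM plus 0.5, 3 g against control, which understates the change of low genes. Each library summed to 1000000 TPM, which keeps no record of read depth, so depth and its counting error are unknown. Between 13219 and 13388 of the 13918 listed genes were above 0 in a library, and the mitochondrial gene mt:CoIII was the highest in every one, at 1.73% to 3.04% of all TPM.

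Of 19 tested salivary glue and early prepupal genes, which normally belong to the end of larval life and the prepupa, 15 were higher at 3 g (camera adjusted p = 3.28e-31, and 0.173 with an estimated correlation). All 10 measured genes of the Eig71E group, which ecdysone induces in the salivary gland, rose. Among them Eig71Ea stood at 3432 ± 1370.1 TPM at 3 g against 4.42 ± 2.15 TPM in controls, a log2 change of 9.52 ± 0.47 (SE, n = 4 pools per group, adjusted p = 2.97e-05, limma). The larval storage protein receptor Fbp1 rose from 83.2 ± 41.9 to 4911 ± 3627 TPM. Of 31 muscle genes 13 were lower (camera adjusted p = 2.46e-15, and 0.504 with an estimated correlation), and 1 to 7 without control replicate 2 or 3 or any one of the pools at 3 g. Among the 13 was flightin (fln), a thick filament protein of flight muscle, with 37.7 ± 8.16 TPM at 3 g against 444 ± 381 TPM in controls. Cuticle protein genes went both ways, with 9 higher and 20 lower of 99 tested. There 3 and 5 were higher without control replicates 2 and 4, and 10 to 13 lower without control replicate 2 or 3 or 3 g replicate 2.

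Of the 12044 genes tested, 516 differed between 3 g and control at an adjusted p under 0.05 (limma with an intensity trend), 268 higher and 248 lower, and 1958 had an unadjusted p under 0.05. A change of at least 2-fold was seen for 373 of them, 220 higher and 153 lower, and one of at least 16-fold for 89, 59 higher and 30 lower. All 4 pools at 3 g lay on the same side of all 4 control pools for each of the 516, as they did for 1505 of all genes tested (12.5%, where chance gives 2.86%). Among the 516, 10 genes formed 5 sets whose members share every value. The libraries were unequal in their weight on this count. It was 162 without control replicate 2, 206 without control replicate 3, 275 without 3 g replicate 2 and 335 without 3 g replicate 4. The genes higher numbered 112, 141, 172 and 161 without control replicates 2, 3 and 4 and 3 g replicate 2, and those lower numbered 50, 65, 114, 104 and 130 without control replicates 2 and 3 and 3 g replicates 2, 3 and 4. The lowest mean correlation with the others of its group was that of 3 g replicate 2 (0.881) at 3 g and that of replicate 4 (0.922) among the controls, while 3 g replicates 3 and 4, at 0.908 and 0.906, lay below the latter. With 3 g replicate 2 and control replicate 4 both left out, a choice made after seeing the data, 228 genes passed, 211 of them among the 516. Of 71 named genes past the threshold, 35 passed without each single library in turn.

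**Figure D1:**
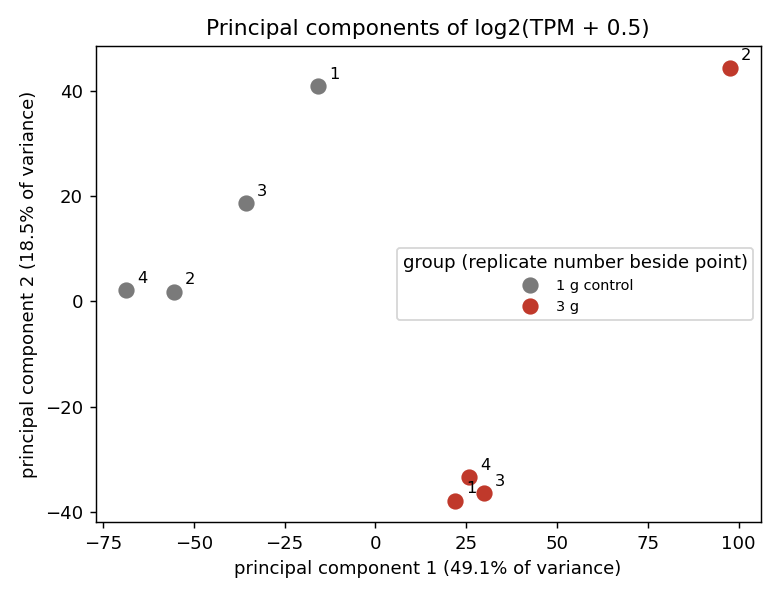
Each point is one library, placed by its first and second principal component of log2(TPM + 0.5), with colour for the group and the replicate number beside it. The first component (49.1% of variance) runs from -68.6 to -15.7 in the controls and from 22.0 to 97.7 at 3 g, where replicate 2 lies apart at 97.7.

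The genes with the largest rise were led by CG4151, with 3533 ± 342 TPM at 3 g against 3.55 ± 0.957 TPM in controls (log2 change 9.80 ± 0.19, SE, adjusted p = 1.10e-07, limma). Of the next 9 by size, 7 were Eig71E genes, and the other 2 were CG33998 (1385 ± 289 against 1.39 ± 0.397 TPM, n = 4) and CG10853 (2352 ± 591 against 4.71 ± 2.097 TPM, n = 4). The list of salivary glue and early prepupal genes, which holds the Eig71E genes, the glue proteins and the larval serum proteins, had 15 of 19 tested members higher, 0 lower and 4 not past the threshold. Adjusted over the list alone, 18 were higher and 0 lower (limma, 18 higher and 0 lower at an unadjusted p under 0.05). Eig71Eg reached 3739.9 ± 1706 TPM at 3 g against 4.47 ± 2.49 TPM in controls, and Eig71Ei, listed at 0 in 1 control pool, 667 ± 484 TPM at 3 g against 0.627 ± 0.607 TPM in controls. The glue protein gene Sgs3 rose from a low level, 7.503 ± 3.64 TPM at 3 g against 0.185 ± 0.138 TPM in controls (adjusted p = 0.00134), and was chosen here after its values were seen. The camera test put this list on the higher side (adjusted p = 3.28e-31), with adjusted p = 0.173 with an estimated correlation. Leaving out any 1 library left 13 to 16 members higher, and leaving out both 3 g replicate 2 and control replicate 4 left 12. The Eig71E genes resemble one another, so that reads shared between them cannot be excluded and the level of each is uncertain.

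Genes of the ecdysone response, which times moulting and metamorphosis, had 2 of 22 members higher, 0 lower and 20 not past. The same counts, 2 higher and 0 lower, were seen adjusted over the list alone (limma, 4 higher and 0 lower at an unadjusted p under 0.05). The members that rose were broad (br), an early ecdysone response transcription factor, with 85.3 ± 42.1 TPM at 3 g against 11.1 ± 3.70 TPM in controls (adjusted p = 0.0104), and ftz-f1, a nuclear receptor of the prepupa, with 61.5 ± 22.0 TPM at 3 g against 14.2 ± 8.72 TPM in controls (adjusted p = 0.0254). The list as a whole did not pass (adjusted p = 0.147, and 0.745 with an estimated correlation). Without control replicate 1, 2 or 3, or 3 g replicate 1 or 2, 1 member passed. In the fat body list 2 of 25 members were higher, 0 lower and 23 not past. The counts were 2 higher and 0 lower adjusted over the list alone (limma, 7 higher and 3 lower at an unadjusted p under 0.05), and 4 were higher without 3 g replicate 1. Both are also members of the list of early prepupal genes. They were Fbp1 and the larval serum protein gene Lsp1gamma, with 985 ± 406 TPM at 3 g against 79.0 ± 11.5 TPM in controls (adjusted p = 7.61e-04). The median of the fat body list was -0.04 and its mean 0.49, and the camera test, on the higher side, did not pass (adjusted p = 0.307). That median lay above 0 without control replicate 4 (0.12), 3 g replicate 1 (0.03) or 3 g replicate 2 (0.0037), without a filter (0.04) and with a minimum of 5 TPM (0.40). The circadian clock list had 0 of 10 members past the threshold over all genes and 0 adjusted over the list alone (limma, 2 at an unadjusted p under 0.05). vri was at 71.2 ± 20.9 against 42.5 ± 20.7 TPM and tim at 2.29 ± 0.574 against 3.96 ± 1.58 TPM. Its median was 0.04, its mean -0.01 and its camera direction higher (adjusted p = 0.918), and the median lay below 0 without control replicate 2 (-0.05) or 4 (-0.03).

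**Figure D2:**
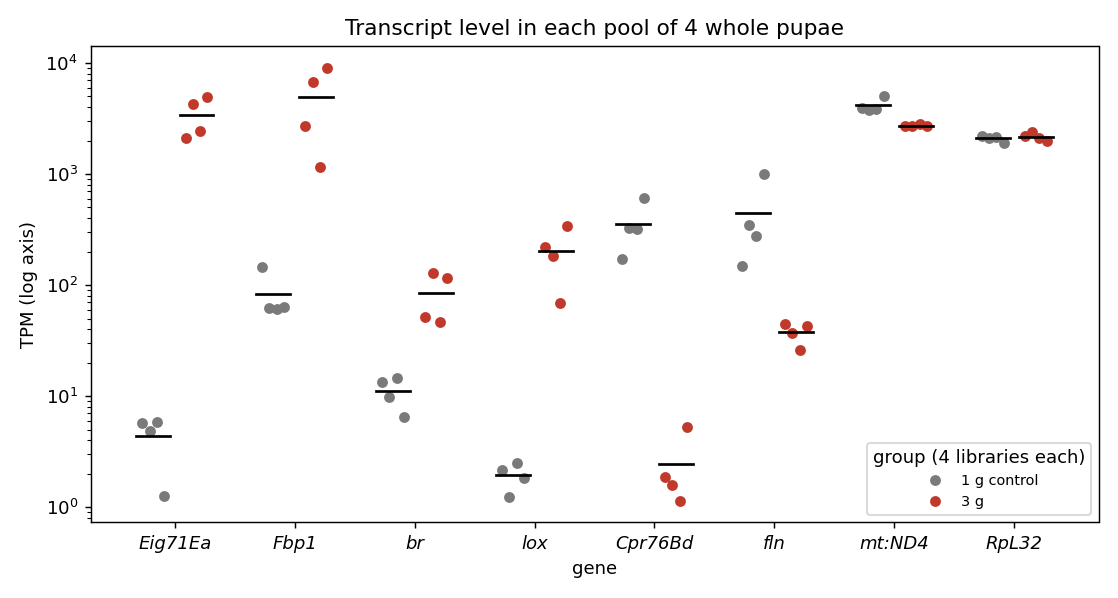
TPM of 8 genes on a log axis, 1 point per pool of 4 whole pupae, grey for 1 g controls and red for 3 g, with a black line at the mean of 4. Eig71Ea, Fbp1, br and lox lie higher at 3 g, Cpr76Bd, fln and mt:ND4 lower, and the groups overlap for RpL32 (2177 ± 184 against 2093 ± 144 TPM).

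Cuticle proteins, the structural proteins laid down with chitin in each new cuticle, went both ways. Of 99 tested members, 9 were higher, 20 lower and 70 not past. Members numbered 17 higher and 24 lower adjusted over the list alone. Cpr76Bd fell to 2.48 ± 1.91 TPM at 3 g against 356 ± 182 TPM in controls (log2 change -6.95, adjusted p = 2.37e-04), and Cpr92F to 9.48 ± 4.15 TPM at 3 g against 547 ± 318 TPM in controls (adjusted p = 7.15e-04). Cpr76Ba, listed at 0 in 1 pool at 3 g, fell to 0.113 ± 0.124 TPM at 3 g against 53.2 ± 42.5 TPM in controls, and Cpr35B rose to 6.22 ± 2.21 TPM at 3 g against 0.247 ± 0.156 TPM in controls (adjusted p = 0.00228). For Cpr30F, which showed the largest fall (log2 change -7.80, adjusted p = 0.00903), control replicate 4 read 3482 TPM and the other 3 controls 85.5 to 381 TPM, while the group means were 1.06 ± 0.372 against 1016 ± 1649.6 TPM. The adult cuticle protein gene Acp65Aa (4.08 ± 3.17 against 1002 ± 1779 TPM) and Cpr64Aa (3.81 ± 1.92 against 1101 ± 1493 TPM) showed the same spread, with control replicate 4 at 3669 and 3325 TPM. The list's median was 0.06, its mean -0.27, and the camera test, on the lower side, did not pass (adjusted p = 0.426). The sign of this median rests on single libraries, since it was -0.49 without 3 g replicate 3, -0.02 without control replicate 2, 0.57 without 3 g replicate 4 and 0.40 without control replicate 4. With a minimum of 5 TPM it was -0.11. Members higher numbered 3 without control replicate 2 and 5 without control replicate 4, and members lower 11, 10 and 13 without control replicate 2, control replicate 3 and 3 g replicate 2. With 3 g replicate 2 and control replicate 4 both left out, 1 was higher and 17 lower. Neighbouring Cpr and Lcp65 genes are similar copies, and their single values are uncertain for that reason.

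Among the genes with the largest falls outside this list were CG34461 (65.1 ± 63.3 against 4562 ± 1410.3 TPM, adjusted p = 7.15e-04), CG7214 (34.3 ± 34.0 against 3460.2 ± 3886 TPM) and CG34205 (4.26 ± 1.08 against 698 ± 996 TPM). Genes of chitin synthesis and remodelling had 2 of 38 members higher, 2 lower and 34 not past. When adjusted over the list alone, 8 were higher and 2 lower. Cda5, a chitin deacetylase, fell to 42.1 ± 5.79 TPM at 3 g against 109 ± 11.6 TPM in controls (adjusted p = 0.00241), and Peritrophin-A fell to 31.0 ± 14.7 TPM at 3 g against 109 ± 20.2 TPM in controls. The chitinase Cht4 rose to 26.1 ± 17.0 TPM at 3 g against 1.58 ± 0.785 TPM in controls (adjusted p = 0.00976), and obst-A, a chitin-binding protein of the cuticle, rose to 881 ± 151 TPM at 3 g against 322 ± 129 TPM in controls. In the camera test the list lay on the higher side (adjusted p = 0.00958), with adjusted p = 0.633 with an estimated correlation. In this list 1 was higher without control replicate 1 or 2 or 3 g replicate 2 or 3, and 1 was lower without any one of control replicates 1 to 4 or 3 g replicates 1 and 2, or after median-of-ratios rescaling. Pigmentation and tanning genes had 1 of 26 higher, 2 lower and 23 not past. The list had 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.472). The yellow family members yellow-d2 (23.4 ± 2.37 against 111 ± 13.5 TPM, adjusted p = 1.05e-04) and yellow-e (14.4 ± 8.26 against 44.6 ± 5.72 TPM) fell and yellow-e2 (8.19 ± 1.29 against 3.74 ± 1.20 TPM, adjusted p = 0.0474) rose. For the gene yellow-e2 the log2 change was 1.07, and 0.88 to 1.19 with 1 library left out. It did not pass without any 1 of the 8 libraries (limma, 0 higher, with 4 to 6 at an unadjusted p under 0.05). Nor did it pass with a pseudocount of 0.1, no filter, a minimum of 5 TPM, a robust fit or quantile normalization (0 higher, with 5 to 8 at an unadjusted p under 0.05). In this list 1 member was lower without control replicate 1, 2, 3 or 4 or 3 g replicate 3.

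Of the 31 larval and adult muscle genes 13 were lower, 0 higher and 18 not past, and 24 were lower and 1 higher adjusted over the list alone (limma, 24 lower and 1 higher at an unadjusted p under 0.05). TpnC4, a troponin C of flight muscle, stood at 97.7 ± 27.0 TPM at 3 g against 460.2 ± 186 TPM in controls (adjusted p = 0.00970). The muscle actin gene Act79B stood at 163 ± 35.3 TPM at 3 g against 852 ± 463 TPM in controls (adjusted p = 0.0132) and the muscle LIM protein gene Mlp60A at 149 ± 22.6 TPM at 3 g against 692 ± 391 TPM in controls (adjusted p = 0.0158). For fln the log2 change was -3.21 ± 0.52 (SE, adjusted p = 0.0165). Camera placed the list on the lower side (adjusted p = 2.46e-15), with adjusted p = 0.504 with an estimated correlation. The mean deviation of the list from its average over all libraries was 1.77 on the log2 scale in control replicate 4, between 0.11 and 0.50 in the other controls, and between -0.90 and -0.53 at 3 g. Members lower numbered 1 without control replicate 2, 5 without control replicate 3, and 6, 7, 5 and 7 without 3 g replicates 1 to 4, and 1 was higher without 3 g replicate 3. With 3 g replicate 2 and control replicate 4 both left out, 13 were lower.

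The list of neuronal genes had 3 of 23 members lower, 0 higher and 20 not past, and 9 lower and 0 higher adjusted over the list alone (limma, 11 lower and 0 higher at an unadjusted p under 0.05). They were Snap25, a protein of synaptic vesicle fusion (15.3 ± 0.849 against 26.5 ± 4.85 TPM, adjusted p = 0.0281), nrv3, a subunit of the sodium pump (60.3 ± 10.3 against 115 ± 26.3 TPM, adjusted p = 0.0358), and the sodium channel gene para (2.33 ± 0.535 against 5.50 ± 1.49 TPM, adjusted p = 0.0367). The camera test put the list on the lower side (adjusted p = 8.51e-06), with adjusted p = 0.633 with an estimated correlation. After median-of-ratios rescaling 0 passed (limma, 13 at an unadjusted p under 0.05) and after quantile normalization 1. Without control replicate 2 or 3, or 3 g replicate 2, 3 or 4, 0 passed (limma, 9 to 11 at an unadjusted p under 0.05). In turn 1 passed without control replicate 1, 6 without 3 g replicate 1 and 1 with 3 g replicate 2 and control replicate 4 both left out.

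In the list of the mitochondrial respiratory chain all 37 members lay below 0 in fold change, under both other scalings as well. Of these 12 passed as lower, 0 as higher and 25 did not pass, with 31 lower and 0 higher adjusted over the list alone (limma, 31 lower and 0 higher at an unadjusted p under 0.05). The genes of complex I on the mitochondrial genome were at 2732 ± 52.8 TPM at 3 g against 4153 ± 593 TPM in controls for mt:ND4 (log2 change -0.59, adjusted p = 0.0254), 1851 ± 73.4 against 2759.6 ± 381 TPM for mt:ND3 and 3149.7 ± 83.3 against 4859 ± 889 TPM for mt:ND1. The nuclear gene CoVb, a subunit of cytochrome c oxidase, was at 217 ± 11.1 against 391 ± 82.8 TPM (adjusted p = 0.0268). In the camera test the list lay on the lower side (adjusted p = 3.84e-21), with adjusted p = 0.504 with an estimated correlation. The mean deviation of this list from its average was 0.66 on the log2 scale in control replicate 4, where the muscle list was also highest (1.77), 0.07 to 0.37 in the other controls and -0.38 to -0.28 at 3 g. The members past the threshold numbered 0 after median-of-ratios rescaling (limma, 31 at an unadjusted p under 0.05). They also numbered 0 without control replicate 2 or 3 or without any one of 3 g replicates 1 to 4 (31 to 33 at an unadjusted p under 0.05). They numbered 18 and 11 without control replicates 1 and 4, 5 without the intensity trend, 4 with 3 g replicate 2 and control replicate 4 both left out, and 1 with the male germline score as a covariate, both chosen after seeing the data.

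Other metabolic groups held no member past the threshold over all genes. Of 17 genes of glycolysis and lactate 0 passed, and 1 was higher and 3 lower adjusted over the list alone (limma, 1 higher and 3 lower at an unadjusted p under 0.05, camera adjusted p = 0.192). The lactate dehydrogenase gene ImpL3 stood at 128 ± 91.6 TPM at 3 g against 33.2 ± 2.86 TPM in controls (adjusted p = 0.0774) and Gapdh1 at 336 ± 52.3 against 595 ± 152 TPM. In this list 1 was lower without control replicate 1 and 1 higher without 3 g replicate 1. Of 29 lipid metabolism genes 0 passed, also adjusted over the list alone (limma, 8 higher and 2 lower at an unadjusted p under 0.05, camera adjusted p = 0.0855). Npc2h was at 28.9 ± 3.70 against 61.2 ± 19.7 TPM and Mtp at 56.7 ± 11.1 against 35.7 ± 5.48 TPM. There 1 was lower without control replicate 1 and 2 were higher without 3 g replicate 3.

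Among genes of immunity, antimicrobial peptides had 3 of 20 members higher, 0 lower and 17 not past. Adjusted over the list alone, 5 were higher and 0 lower (limma, 5 higher and 0 lower at an unadjusted p under 0.05). The drosomycin-like genes Drsl1, listed at 0 in 1 control pool, and Drsl6, listed at 0 in 2, rose. They reached 218 ± 73.2 TPM at 3 g against 2.60 ± 2.40 TPM in controls (adjusted p = 0.00360) and 57.4 ± 44.1 TPM at 3 g against 0.312 ± 0.468 TPM in controls. The peptide gene Mtk rose to 38.8 ± 14.1 TPM at 3 g against 9.93 ± 5.73 TPM in controls (adjusted p = 0.0323). Camera placed the list on the higher side (adjusted p = 0.00390), with adjusted p = 0.661 with an estimated correlation, and 1 member was higher with 3 g replicate 2 and control replicate 4 both left out. The mean deviation of this list from its average was 1.46 and 1.13 on the log2 scale in 3 g replicates 2 and 3. It was -0.27 and 0.13 in 3 g replicates 1 and 4, and -1.28 to 0.11 in the controls. Of 8 Bomanin and immune-induced peptides 1 was higher, 0 lower and 7 not past. The counts were 1 higher and 0 lower adjusted over the list alone (limma, 1 higher and 0 lower at an unadjusted p under 0.05). IM10 stood at 43.9 ± 20.3 against 5.44 ± 2.34 TPM (adjusted p = 0.0156). The camera test gave adjusted p = 0.0433 on the higher side for it, and adjusted p = 0.661 with an estimated correlation. The mean deviation of the list from its average was 2.01 and 2.20 on the log2 scale in 3 g replicates 2 and 3, while 3 g replicates 1 and 4 (-0.99 and -0.66) lay within the range of the controls (-1.09 to -0.24). IM10 did not pass without control replicate 2 or 3, or with 3 g replicate 2 and control replicate 4 both left out (limma, 0 members, with 1 at an unadjusted p under 0.05), and 2 members passed without 3 g replicate 1.

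Immune recognition and Toll and Imd signalling genes had 0 of 35 members past the threshold. Members numbered 1 higher and 1 lower adjusted over the list alone (limma, 5 higher and 1 lower at an unadjusted p under 0.05). The peptidoglycan receptor gene PGRP-SA was at 56.2 ± 14.4 against 27.5 ± 4.13 TPM (adjusted p = 0.0554) and GNBP2 at 7.30 ± 1.11 against 11.1 ± 0.616 TPM. The camera test put this list on the higher side (adjusted p = 0.0134), with adjusted p = 0.661 with an estimated correlation, and 1 member was higher without 3 g replicate 1. Of 6 Turandot stress peptides 0 passed and 1 was higher adjusted over the list alone (limma, 2 higher at an unadjusted p under 0.05, camera adjusted p = 0.192). TotA was at 263 ± 109 TPM at 3 g against 49.9 ± 45.7 TPM in controls (adjusted p = 0.0515) and TotC at 4.36 ± 0.571 against 2.52 ± 1.24 TPM. In this list 1 was higher without control replicate 1 and 1 without 3 g replicate 3. Of 18 serpins, inhibitors of serine proteases, 1 was higher, 0 lower and 17 not past. When adjusted over the list alone, 1 was higher and 1 lower (limma, 5 higher and 1 lower at an unadjusted p under 0.05). Spn55B stood at 62.3 ± 2.61 against 24.7 ± 7.34 TPM (adjusted p = 0.0122). In the camera test the serpins lay on the higher side (adjusted p = 0.0228), with adjusted p = 0.504 with an estimated correlation. Among serpins 1 was lower without control replicate 1 and 2 were higher without 3 g replicate 3.

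Serine proteases and digestive enzymes had 2 of 30 members higher, 1 lower and 27 not past, with the same counts adjusted over the list alone (camera adjusted p = 0.0694). The gut protease genes Jon65Aiv (68.0 ± 71.1 against 2.42 ± 2.65 TPM) and Jon65Ai (56.7 ± 50.8 against 0.152 ± 0.107 TPM, listed at 0 in 1 control pool) rose and the trypsin gene kappaTry (1.78 ± 0.866 against 8.13 ± 1.36 TPM, adjusted p = 0.0202) fell. Both Jon65A genes are near copies of one another and their values are uncertain. Without control replicate 1, 2, 3 or 4, or 3 g replicate 2 or 4, 0 members were higher (limma, 5 to 9 at an unadjusted p under 0.05), and 1 was higher without 3 g replicate 3. The members lower numbered 0 without control replicate 2, 3 or 4 (limma, 2 at an unadjusted p under 0.05). After median-of-ratios rescaling or with a pseudocount of 1, 1 was higher, and with a minimum of 5 TPM 0 were lower (1 at an unadjusted p under 0.05).

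Genes that sense or bear mechanical load are of interest in a study of gravity. Of 48 mechanosensory and gravity-sensing channel genes in the list, 19 reached a mean of 1 TPM and were tested, and 0 of these passed the threshold. The rest were too low to be tested, so the list says nothing of them. The list had 2 higher and 1 lower adjusted over the list alone (limma, 5 higher and 2 lower at an unadjusted p under 0.05). The stretch-gated channel gene Piezo was at 17.5 ± 2.08 TPM at 3 g against 11.1 ± 1.66 TPM in controls (adjusted p = 0.0563). The gene trp, for a channel of photoreceptors, was at 4.76 ± 3.18 TPM at 3 g against 37.1 ± 29.6 TPM in controls (adjusted p = 0.0580). The list had a median of -0.13 and a mean of -0.11, while its camera direction was higher (adjusted p = 0.721). The median lay above 0 without 3 g replicate 2 (0.08) or control replicate 2 (0.02) and with a minimum of 5 TPM (0.04). With the replicate block 1 member of this list was lower, and with sample weights 3 were higher and 1 lower. Of 31 genes of the cytoskeleton and force-bearing adhesion 0 passed, also adjusted over the list alone (limma, 5 higher and 0 lower at an unadjusted p under 0.05). The actin gene Act42A was at 893 ± 49.6 against 705 ± 83.6 TPM and sqh, a light chain of non-muscle myosin, at 364 ± 55.5 against 273 ± 39.3 TPM. Camera placed that list on the higher side (adjusted p = 0.0227), with adjusted p = 0.661 with an estimated correlation.

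The extracellular matrix list had 2 of 20 members higher, 0 lower and 18 not past. Adjusted over the list alone, 2 were higher and 0 lower (limma, 3 higher and 2 lower at an unadjusted p under 0.05). The lysyl oxidase gene lox, whose enzyme class crosslinks matrix proteins, rose to 204 ± 112 TPM at 3 g against 1.95 ± 0.543 TPM in controls (log2 change 6.20, adjusted p = 3.50e-04). Timp, an inhibitor of matrix metalloproteinases, rose to 71.9 ± 11.1 TPM at 3 g against 28.3 ± 3.01 TPM in controls (adjusted p = 0.00385). Both passed without any 1 of the 8 libraries, and 1 member was lower without 3 g replicate 1. The median of the list was -0.11, its mean 0.35 and its camera direction higher (adjusted p = 0.728). Ion channels and transporters had 5 of 67 members higher, 3 lower and 59 not past. The counts were 12 higher and 16 lower adjusted over the list alone (camera adjusted p = 0.402). The bestrophin gene Best2 (28.7 ± 7.74 against 12.3 ± 1.04 TPM), the chloride channel gene ClC-a (15.7 ± 4.25 against 6.41 ± 0.325 TPM) and the potassium channel gene Irk2 (17.6 ± 10.98 against 3.81 ± 0.725 TPM) rose. The cation channel gene NaCP60E (4.79 ± 0.638 against 9.46 ± 0.986 TPM, adjusted p = 0.0137) fell. Members higher numbered 0 without control replicate 2, 3 or 4 or 3 g replicate 2 (limma, 12 to 14 at an unadjusted p under 0.05), 2 without 3 g replicate 1, 1 without 3 g replicate 4 and 3 after quantile normalization. Members lower numbered 0 without control replicate 2 (17 at an unadjusted p under 0.05), 1 without control replicate 1 or 3 or 3 g replicate 2, 3 or 4, 9 without 3 g replicate 1, and 1 under either other scaling. Of 32 subunits of the proton-transporting V-ATPase 0 passed, also adjusted over the list alone (limma, 8 higher and 1 lower at an unadjusted p under 0.05). Vha68-1 stood at 33.9 ± 4.07 against 47.3 ± 5.33 TPM and Vha16-1 at 527 ± 53.2 against 392.2 ± 43.0 TPM. The median of that list was 0.13, its mean -0.02 and its camera direction higher (adjusted p = 0.0569).

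Lists of stress and detoxification genes held either no member past the threshold or a share not far from that of all genes tested (516 of 12044). Of 25 heat shock proteins and chaperones 0 passed, also adjusted over the list alone (limma, 2 higher and 2 lower at an unadjusted p under 0.05, camera adjusted p = 0.797). The small heat shock protein gene l(2)efl was at 65.8 ± 38.9 against 158 ± 37.3 TPM and Hsp67Bb at 166 ± 84.6 against 70.9 ± 12.4 TPM. Of 33 glutathione S-transferases 0 passed, also adjusted over the list alone (limma, 1 higher and 4 lower at an unadjusted p under 0.05, camera adjusted p = 0.231). GstS1 stood at 457 ± 87.6 against 752 ± 207 TPM and GstT3 at 82.0 ± 24.4 against 125 ± 18.3 TPM. Antioxidant and redox enzymes had 1 of 34 members higher, 0 lower and 33 not past. Members numbered 1 higher and 0 lower adjusted over the list alone (limma, 3 higher and 5 lower at an unadjusted p under 0.05). The member was the transferrin gene Tsf3 (25.5 ± 1.68 against 12.9 ± 2.55 TPM, adjusted p = 0.0156), which did not pass without control replicate 2. The median of that list was 0.01, its mean 0.00 and its camera direction lower (adjusted p = 0.978), and its median fell below 0 under both other scalings (-0.02 and -0.01) and without control replicate 2 (-0.03), control replicate 4 (-0.07) or 3 g replicate 2 (-0.03). Cytochrome P450s had 3 of 67 members higher, 1 lower and 63 not past. When adjusted over the list alone, 4 were higher and 3 lower (camera adjusted p = 0.753). Cyp304a1 (53.9 ± 6.06 against 8.82 ± 1.35 TPM, adjusted p = 7.79e-05), Cyp309a1 (52.7 ± 16.9 against 17.7 ± 4.76 TPM) and Cyp6d4 (44.1 ± 5.22 against 23.7 ± 5.77 TPM) rose and Cyp4g15 (8.00 ± 1.79 against 18.1 ± 4.72 TPM, adjusted p = 0.0323) fell. In this list 1 was higher after quantile normalization and without control replicate 2 or 3 or 3 g replicate 2 or 4. There 0 were lower under either other scaling and without control replicate 1, 2 or 3 or 3 g replicate 2, 3 or 4 (limma, 7 to 12 at an unadjusted p under 0.05), and 2 without 3 g replicate 1.

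Juvenile hormone and insulin signalling genes had 1 of 23 members higher, 0 lower and 22 not past. The list had 3 higher and 0 lower adjusted over the list alone (limma, 5 higher and 0 lower at an unadjusted p under 0.05). The member was Jhe, the esterase that breaks down juvenile hormone, with 269 ± 87.3 TPM at 3 g against 41.1 ± 13.02 TPM in controls (adjusted p = 0.00491), and 2 members passed without 3 g replicate 3 or 4. The camera test put the list on the higher side (adjusted p = 0.00212), with adjusted p = 0.633 with an estimated correlation. Cell death and autophagy genes had 2 of 33 members higher, 0 lower and 31 not past. Adjusted over the list alone, 3 were higher and 0 lower (limma, 12 higher and 0 lower at an unadjusted p under 0.05). They were skl, an activator of apoptosis, with 12.4 ± 2.66 TPM at 3 g against 4.83 ± 1.54 TPM in controls (adjusted p = 0.0259), and the autophagy gene Atg18b with 33.6 ± 7.41 TPM at 3 g against 18.0 ± 2.00 TPM in controls (adjusted p = 0.0361). In the camera test the list lay on the higher side (adjusted p = 8.51e-06), with adjusted p = 0.633 with an estimated correlation. After quantile normalization 0 passed, as without control replicate 2 or 3 or 3 g replicate 2 or 4 (limma, 8 to 10 at an unadjusted p under 0.05), and 1 passed after median-of-ratios rescaling and without control replicate 4 or 3 g replicate 1.

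Housekeeping groups held no member past the threshold. Of 47 proteasome genes 0 passed, also adjusted over the list alone (limma, 17 higher and 0 lower at an unadjusted p under 0.05). The subunit gene Rpt1 was at 167 ± 24.1 against 124 ± 8.36 TPM and Rpn3 at 135 ± 22.1 against 100.0 ± 10.03 TPM. Camera placed the proteasome on the higher side (adjusted p = 1.82e-04), with adjusted p = 0.661 with an estimated correlation. Its median log2 change was 0.22 and its mean 0.06. The mean deviation of the list from its average was 0.10, -0.43, 0.07 and 0.38 on the log2 scale in 3 g replicates 1 to 4. In the controls it ran from -0.18 to 0.14. Of 93 ribosomal protein genes 0 passed, also adjusted over the list alone (limma, 0 at an unadjusted p under 0.05). RpL5 stood at 2849.8 ± 325 against 2432 ± 194 TPM and RpS28a at 6.07 ± 3.48 against 11.6 ± 5.31 TPM. By camera these genes lay on the higher side (adjusted p = 0.0228), with adjusted p = 0.814 with an estimated correlation. The camera direction turned to the lower side without 3 g replicate 2, with a mean log2 change of 0.02. Of 32 genes of DNA replication and mitosis 0 passed, also adjusted over the list alone (limma, 0 at an unadjusted p under 0.05, camera adjusted p = 0.674). Orc6 was at 4.88 ± 1.05 against 3.92 ± 1.25 TPM and the mitotic kinase gene aurA at 24.0 ± 8.09 against 27.8 ± 4.73 TPM. The median of this list was -0.04 and turned to 0.01 after quantile normalization, 0.01 without control replicate 1, 0.03 without control replicate 3 and 0.02 without 3 g replicate 4. Of the reference genes, RpL32 was at 2177 ± 184 against 2093 ± 144 TPM (log2 change 0.06), Act5C at 2861 ± 248 against 2224 ± 637 TPM (0.40), alphaTub84B at 3980.0 ± 500.2 against 3867 ± 357 TPM (0.04) and Gapdh2 at 387 ± 79.1 against 387 ± 51.9 TPM (-0.01), none past the threshold. The signs of RpL32, alphaTub84B and Gapdh2 turned after quantile normalization.

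Germline genes were marked by 1 library. Of 45 male germline and male-specific genes 0 passed, also adjusted over the list alone (limma, 0 at an unadjusted p under 0.05). The Y-linked gene Ory stood at 1.73 ± 0.881 against 2.70 ± 0.892 TPM and janA at 138 ± 29.4 against 161 ± 9.52 TPM. The camera test put the list on the lower side (adjusted p = 0.00670), with adjusted p = 0.814 with an estimated correlation, and over all 8 libraries the median log2 change was -0.60 and the mean -0.48, with 42 of 45 members below 0. The mean deviation of this list from its average was -1.77 on the log2 scale in 3 g replicate 2 and between 0.19 and 0.32 in the other 3 pools at 3 g. With this library and control replicate 4 left out the mean log2 change of the male germline list was 0.13. Of 12 female germline genes 0 passed, also adjusted over the list alone (limma, 0 higher and 1 lower at an unadjusted p under 0.05, camera adjusted p = 0.426). grk was at 16.3 ± 3.47 against 22.9 ± 3.22 TPM and me31B at 147 ± 1.87 against 131 ± 14.2 TPM. The hemocyte list, taken by symbol as markers of blood cells though its members need not be particular to them, had 1 of 22 higher, 3 lower and 18 not past. The counts were 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.369). The scavenger receptor gene Sr-CI (63.8 ± 9.27 against 31.4 ± 3.43 TPM, adjusted p = 0.0104) rose. The genes NimB2 (9.35 ± 1.64 against 17.7 ± 2.70 TPM), NimB5 (2.31 ± 0.981 against 7.24 ± 2.95 TPM) and the prophenoloxidase gene PPO2 (0.975 ± 0.196 against 2.35 ± 0.565 TPM) fell. The members lower numbered 0 after quantile normalization and without any one of control replicates 1 to 4 or 3 g replicates 2 and 3 (limma, 5 to 6 at an unadjusted p under 0.05). They numbered 1 after median-of-ratios rescaling, with a minimum of 5 TPM and without 3 g replicate 4. Odorant binding and chemosensory proteins had 1 of 26 members higher, 0 lower and 25 not past. Members numbered 1 higher and 0 lower adjusted over the list alone (limma, 1 higher and 2 lower at an unadjusted p under 0.05, camera adjusted p = 0.330). The member was Obp56d, with 112 ± 68.3 TPM at 3 g against 7.13 ± 1.49 TPM in controls (adjusted p = 0.00400). In this list 1 was lower after median-of-ratios rescaling and without 3 g replicate 1 or 3.

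**Figure D3:**
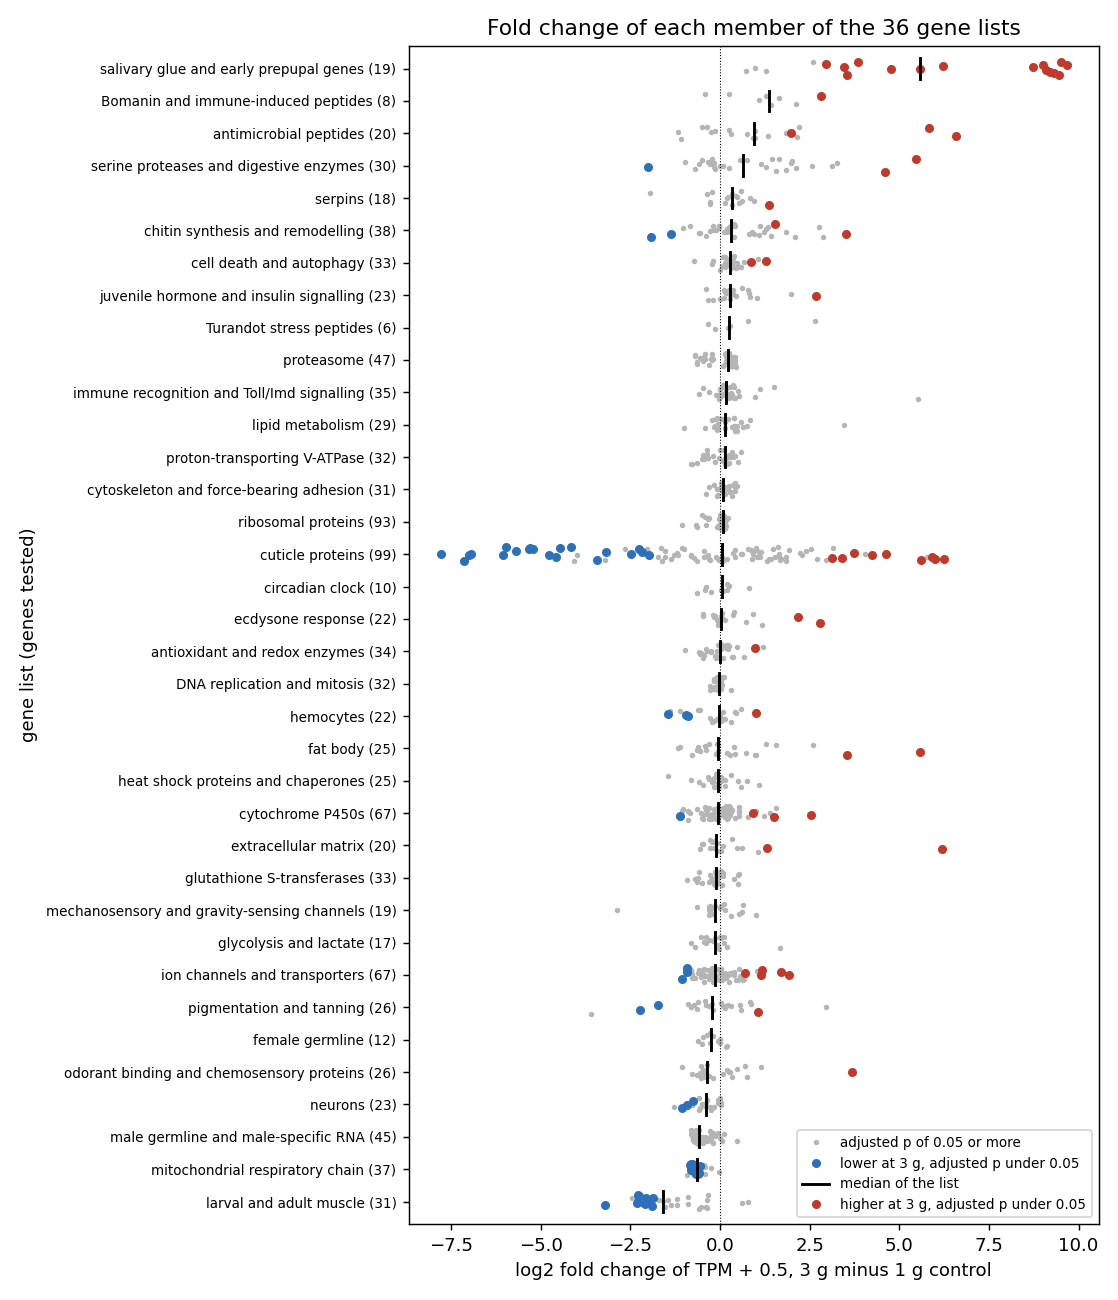
Log2 fold change of TPM + 0.5, 3 g minus 1 g control, for each tested member of the 36 gene lists, with a black bar at the median of a list and colour for members at an adjusted p under 0.05. Medians run from -1.60 for muscle to 5.58 for the salivary glue and early prepupal genes, and the cuticle proteins spread to both sides, with 9 higher and 20 lower.

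Of the 36 lists, 15 passed the camera test with a preset correlation of 0.01, 11 on the higher side and 4 on the lower. With a correlation estimated from these libraries 0 passed (limma camera, 3 at an unadjusted p under 0.05). The fry test, which asks whether the genes of a list move one way on balance, passed for 2 lists, the salivary glue and early prepupal genes and the mitochondrial respiratory chain. Its mixed form, for change in either direction, passed for 26.

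Counts of list members also moved in the 2 fits chosen after seeing the data. With 3 g replicate 2 and control replicate 4 both left out, 0 members were higher among serpins, antioxidant enzymes, pigmentation genes and hemocyte genes (limma, 1 to 3 at an unadjusted p under 0.05). Likewise 0 were higher among serine proteases, chitin genes, cell death genes and ion channels (limma, 5 to 13 at an unadjusted p under 0.05), and 1 among cytochrome P450s. Lower were 0 cytochrome P450s, serine proteases, ion channels and hemocyte genes (limma, 2 to 15 at an unadjusted p under 0.05), and 1 each of the chitin and pigmentation genes. With the male germline score as a covariate, 5 muscle genes were lower, as were 11 cuticle protein genes and 1 each of the neuronal, chitin, ion channel and hemocyte genes. In that fit 5 cuticle protein genes, 2 ion channels and 1 each of the cytochrome P450s, chitin genes and cell death genes were higher. No serine protease or pigmentation gene was higher and no cytochrome P450 lower there (limma, 0 of each, with 4 to 10 at an unadjusted p under 0.05).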

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

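The tests of sex and of stage in the last paragraph were chosen only after the low value they concern had been seen. Within each group of 4, a library was singled out where its gap to the nearest other, divided by the whole range, was above Dixon's critical value at 95%. For genes this was done on log2(TPM + 0.5). Chance alone marks about 1 in 20 groups. Of 210 pairs of a gene and a group 17 were marked, and of 72 pairs of a list score and a group 6.

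At 3 g, CG4151 read 3024 TPM in replicate 1 against 3667 to 3760.2 TPM in the other 3, and PGRP-SA 34.6 against 61.3 to 65.2 TPM in the same replicate. Orc6 read 3.31 TPM in replicate 1 against 5.23 to 5.57. In replicate 2, RpS28a read 0.95 TPM against 7.14 to 8.75, and Ory 0.420 against 2.04 to 2.34. In replicate 3, kappaTry read 0.510 TPM against 1.98 to 2.41, and ClC-a 9.35 against 17.5 to 18.3. In replicate 4, CG34461 read 159.9 TPM against 29.96 to 37.8.

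In the controls, Fbp1 read 146 TPM in replicate 1 against 61.1 to 63.7 in the other 3, and Eig71Eg 0.820 in replicate 2 against 4.91 to 6.08. In replicate 3, Mtk read 18.5 TPM against 6.69 to 7.41, and Obp56d 9.36 against 6.20 to 6.53. Control replicate 4 was marked for 5 genes: Eig71Ea (1.26 TPM against 4.88 to 5.83), Cyp4g15 (25.1 against 15.3 to 16.2), mt:ND4 (5036 against 3773 to 3943), Rpt1 (112 against 127 to 129) and nrv3 (154 against 99.3 to 104).

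Of the list scores, on the log2 scale, Turandot stress peptides stood at -0.43 in 3 g replicate 4 against 0.45 to 0.59 in the other 3, V-ATPase subunits at -0.44 in 3 g replicate 2 against 0.09 to 0.18, and ecdysone response genes at -0.32 in 3 g replicate 3 against 0.38 to 0.42. DNA replication and mitosis genes stood at 0.495 in 3 g replicate 3 against -0.26 to -0.17, and pigmentation and tanning genes at 0.51 in control replicate 4 against -0.06 to 0.04.

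The male germline score was -1.77 in 3 g replicate 2 against 0.19 to 0.32 in the other 3 pools at 3 g and -0.34 to 0.61 in the controls. If an earlier stage of all pools at 3 g lowered that score, it would be low in the other 3 as well. They fell short of the controls by a share of -0.014 of the shortfall of replicate 2 (2.01 on the log2 scale), so the low score was not shared. No sample of known age shows whether stage lowers this score. The test therefore cannot decide on an earlier stage, and an earlier stage of replicate 2 alone was not tested. Fewer male pupae in this pool may be a cause: the Y-linked genes kl-2, kl-3, kl-5 and Ory summed to 1.29 TPM there, 0.17 of the median of the other 3. Fewer males cannot be told apart from a smaller share of germline of both sexes, because the female germline score was also low in this pool (-0.78 against -0.04 to 0.22), and because those Y-linked genes are themselves testis transcripts. Without this pool the male germline score at 3 g differed from that of the controls by 0.0278, and an effect of 3 g on this pool alone was not tested.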

How the results depend on the processing

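The fits that leave out 3 g replicate 2 with control replicate 4, that take the male germline score as a covariate, and that count genes of identical values once were chosen only after the results had been seen. Of 71 named genes past the threshold, 71 kept their direction under each of the alternatives run. Under the whole-group settings other than sample weights and the block, 49 stayed past, 35 under each single library left out, 40 with both libraries left out and 49 with the covariate. Of 15 lists past the threshold, 13 kept their direction under each alternative run, the exceptions being ribosomal proteins and male germline genes, and 11 stayed past under those whole-group settings, 7 under each single library left out, 6 with both left out and 7 with the covariate. Of the 34 named genes not past, 14 passed under at least 1 alternative, as did 9 of the 21 lists. Both other scalings moved the median fold change of all genes by less than 0.1. Median-of-ratios rescaling gave 382 changed genes, 356 of them among the 516, and quantile normalization 401, with 380 shared. Counting genes of identical values once gave 511. Depth is unknown in TPM, so its limits on low genes were not assessed.

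Leaving out 1 library gave 162 to 479 changed genes, 112 to 248 higher, 50 to 245 lower and 8 to 17 lists, in part through fewer samples. With 3 g replicate 2 and control replicate 4 left out, 228 genes changed, 108 higher and 120 lower, and 7 lists passed. With the male germline score as a covariate 340 changed, 145 of them lower, and 9 lists passed. Sample weights gave 1193 changed genes, 505 higher and 688 lower, and 9 lists, with 1 library, control replicate 3, weighted at 34.3 and the others at 0.225 to 1.09, and the estimation of the weights stopped before it converged. With an estimated correlation 0 lists passed (limma camera, 3 at an unadjusted p under 0.05, and 2 by fry). For the lists past the preset test the estimates lay above the preset 0.01, from 0.04 for serpins to 0.88 for male germline genes. They were 0.44 for the prepupal genes, 0.53 for the respiratory chain and 0.57 for muscle. Where genes of a list vary together this much, the p-values of the preset test are likely too small. For the covariate and the weights the cause was not tested.

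No sign was seen that replicate numbers pair the libraries. The deviations of same-numbered libraries correlated at -0.38, -0.52, 0.06 and 0.08 across genes, which are not independent replicates, and not every library correlated best with its own number. Deviations from the mean of a small group constrain one another, so a shared day or batch cannot be excluded. With the replicate block 147 genes changed, 87 higher and 60 lower, and 140 of them were among the 516, with fewer residual degrees of freedom, while 16 lists passed.

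Directions turned for results that had not passed, apart from 2 lists, and the cause was not tested. Values are log2 fold changes of genes and mean log2 fold changes of lists, and for a list it is the camera direction that turned, which can part from the sign of its mean. Without a filter these were mechanosensory channels (-0.0814) and the circadian clock (-0.0375), with a minimum of 5 TPM hemocytes (0.0143), and without the trend antioxidant enzymes (0.0028). After quantile normalization they were RpL32 (-0.013), alphaTub84B (-0.0253) and Gapdh2 (0.022). With sample weights they were Orc6 (-0.1857), RpL32 (-2e-04), alphaTub84B (-0.0406), the circadian clock (-0.082) and fat body (0.292). With both libraries left out they were aurA (0.0155), RpL32 (-0.0435), alphaTub84B (-0.0636), the circadian clock (-0.0651), ribosomal proteins (-0.0246), male germline (0.1335) and female germline (0.0561). With the covariate they were extracellular matrix (0.3158), the circadian clock (-0.0339) and female germline (0.0168). With 1 library left out, results that turned at least once ranged from -0.1994 to 0.1383 for heat shock proteins, -0.0624 to 0.0751 for antioxidant enzymes, -0.2261 to 0.0247 for DNA replication, -0.104 to 0.0933 for Gapdh2, 0.2986 to 0.4453 for extracellular matrix, -0.0604 to 0.0831 for the circadian clock and -0.0311 to 0.125 for alphaTub84B. The range was -0.0333 to 0.012 for cytochrome P450s, -0.3642 to -0.0892 for pigmentation, -0.5697 to -0.0781 for cuticle proteins, -0.4066 to 0.0178 for aurA, -0.0204 to 0.0387 for ribosomal proteins, -0.1059 to -0.014 for ion channels and -0.2332 to -0.0371 for mechanosensory channels.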

Other observations

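The tests in this part were chosen only after the results they bear on had been seen, apart from the share of neighbouring pairs with overlapping gene models. Gene families were formed by symbol with at least 8 tested members, 58 in all, and each was tested for an excess of higher and of lower genes by a one-sided Fisher's exact test. Of 116 such tests 3 passed after adjustment. In the mRpL family, genes of the large subunit of the mitochondrial ribosome, 15 of 47 were lower (adjusted p = 8.06e-13), and all 47 lay below 0 in fold change in each of the 13 settings run. Genes within a family are not independent of one another, so the p-values of all families given here are too small. mRpL42 stood at 48.1 ± 1.71 TPM at 3 g against 85.7 ± 11.1 TPM in controls (log2 change -0.82), mRpL34 at 58.5 ± 2.103 against 90.1 ± 7.93 and mRpL21 at 28.6 ± 1.68 against 43.2 ± 1.62 (n = 4 each). The count was 0 without control replicate 2 (limma, 31 at an unadjusted p under 0.05), 1 without control replicate 3, 10 without control replicate 1, and 2 without 3 g replicate 2, 3 or 4, and it was 17 and 9 under median-of-ratios and quantile scaling. With 3 g replicate 2 and control replicate 4 both left out it was 3. Without control replicate 4, where the muscle list and the list of the respiratory chain were highest, it was 12, and whether the mRpL genes changed apart from muscle was not tested further. Of the 26 mRpS genes of the small subunit 3 were lower (adjusted p = 0.306), among them mRpS35 at 21.9 ± 0.637 against 34.5 ± 2.54 TPM. The other families past the test were Eig, with 10 of 10 higher (adjusted p = 2.92e-15), and Cpr, with 16 of 62 lower (adjusted p = 2.93e-12) and 5 higher. The Cpr count of lower genes was 10 without control replicate 2 or 3 and with the male germline score as a covariate.

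The count of changed genes stood out among splits of these libraries, but chance could not be excluded as the source of the count of lists. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one with 516 genes, gave a count as large, and the highest of the others was 32. For lists, 19 of the 35 splits gave as many as the real 15 or more, and the highest of the others was 27.

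At 3 g 15 of 19 prepupal genes were higher and 13 of 31 muscle and 20 of 99 cuticle protein genes lower, while 9 cuticle protein genes were higher. An earlier developmental stage of the 3 g pools may account for the rise of the prepupal genes and for these falls. If so, the same genes might part between controls that differ in age, and in 4 of the 6 pairs of controls the higher and lower genes, called without that pair (51 to 152 genes), parted by more than in 95 of 100 random matched sets (gaps of 17.2 to 66.1 percentage points over the 6 pairs, random values of 17.9 to 34.9). That is fewer than the 5 pairs asked for, and no sample of known age is at hand, so an earlier stage cannot be told apart from a direct effect of 3 g on these genes, which is untested (a first form of this test looked only at controls 1 and 4, whose gap is the largest of the 6). The random sets were matched on mean level only. Genes that vary together can part by more than such sets whatever the cause. The 6 pairs also share libraries and are not independent results. Dilution by the higher genes is argued against: they took 6.99 ± 1.499% of TPM at 3 g against 0.654 ± 0.109% in controls, which lowers all other genes by a log2 value of -0.0951, far from the median of -1.29 among the lower genes. Larval tissue diluting all others by as much as the median fall of -1.29 would be expected to lower the male germline score. In 3 g replicates 1, 3 and 4 that score differed from controls by 0.0278 (control SD 0.443). The score cannot decide on such dilution, since the sexes in the pools are unknown and the controls themselves spread. Nor does any sample of known age show how stage moves it. Neuron scores were lower in these pools, at 0.08, -0.25 and -0.39 against 0.16 to 0.26 in controls. Dilution also stays open in replicate 2, where the male germline, female germline and neuron scores differed from the control mean by -2.01, -0.88 and -0.51. There it cannot be told apart from other causes of the low germline scores (over all 4 pools the mean log2 change of the male germline list was -0.48).

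Changed genes lay beside each other in the genome more often than placed at random. With genes of identical values counted once, which was done after a first count that kept them apart, 46 neighbouring pairs among 504 placed genes changed in the same direction (30 both higher, 16 both lower), against a mean of 10.7 and a highest of 25 in 10000 random placements (one-sided permutation p = 0.0001, the smallest they can give). Without the Eig71E genes, whose 10 members form the longest run, 37 such pairs remained against a highest of 23, while 16 pairs of all placed genes changed in opposite directions, against a mean of 10.7 and a highest of 24 (one-sided permutation p = 0.0765). Overlapping gene models argue against shared reads as the whole cause, since they held for 6.5% of the pairs. Shared control of neighbours may contribute, while reads shared between tandem copies with no overlap were not tested.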
